A study of Mus musculus with 45 samples.

How the data were processed

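Gene expression was measured by bulk RNA sequencing of liver lysate from wild-type mice in 45 libraries. Per the submitters' processing notes, RNA was isolated with a spin-column kit, libraries were made with a stranded mRNA kit and the genome build was mm10. The aligner, counter, annotation and filters are not given in the sources used here. The authors deposited 1 table with 24972 genes and 45 libraries. Its values are deposited as TPM. Each library sums to between 999999 and 1000001, and the smallest value of a gene falls with its exon length (Spearman rho = -0.66 over 1979 genes), although the table is named as normalized counts. TPM hide the sequencing depth, so the counting precision per library is unknown and whole reads cannot be recovered. Of the table, 26 entries whose names had turned into calendar dates (0.044% of TPM) were left out, among them the 4 entries that share a name. That gave 24946 usable genes, of which 5940 were at 0 in every library and 24817 names were found in GENCODE M21 or RefSeq. Gene coordinates are from GENCODE M21.

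Values were taken as log2(TPM + 0.5), and the 11244 genes with a mean of at least 0.5 TPM, which hold 99.88% of TPM, were tested. This is the setting that had been written for values scaled to a fixed total. The test was limma 3.58.1 in R 4.3.3 with a mean for each of the 12 groups of stage, diet and sex labels. Its moderated variance used a trend with the mean (33 residual and 3.8 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene is called at an adjusted p under 0.05. Diet effects are the ethanol-labelled minus the control-labelled mean, averaged over the sex labels. Sex differences are the male-labelled minus the female-labelled effect, and changes are the later minus the earlier stage. A library counts as in the direction of a difference when it lies on that side of the mean of the other label within the same stage and remaining label. Changes given relative to an all-gene shift come from the same test after median-of-ratios scaling. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

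The comparisons, tests, 38 lists of genes, rule for naming genes and most other settings were chosen before the data were examined. The comparison of female-labelled with male-labelled libraries, its change between stages, its counts within each diet label at peak and median-of-ratios scaling were added afterwards. Of the lists 37 had members tested. Lists were tested with camera at an inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry, adjusted over the lists within a comparison. Counts of list members are given over all genes and when adjusted over the list alone.

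By the naming rule, for each diet comparison the 10 largest called differences each way that held in both sex labels could be named. So could the 4 members of each list with the smallest p, and Cyp2e1, Adh1, Aldh2 and Alb. For the interactions, stage changes and the comparison of controls the rule took the 5 largest called each way, and for controls also the sex-chromosome genes. Rankings used genes with a mean above the median of 6.34 TPM. They left out 503 clone or model names. The text names fewer genes than the rule allows. Genes whose calls depended on many single libraries are mostly counted and not named, a choice made after those values were seen.

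The alternatives were a pseudocount of 0.1 or 2, no filter or a mean of at least 5 TPM, quantile normalization, division by library totals, median-of-ratios scaling, no variance trend or a robust trend, array weights, the libraries of a stage or of a stage and sex alone, the replicate number as a block, each library left out in turn, a log2 difference of at least 1 and a false discovery rate of 0.01. The replicate block left out 3 libraries without a partner and had 15 residual degrees of freedom. Whether replicate numbers pair the libraries was checked by correlation. The 21 pairs had r from -0.371 to 0.25 with a median of -0.053, and 7 correlated best with their own number. These were all 4 peak female pairs (r from 0.109 to 0.222) and 3 of the 4 early male pairs (r from 0.151 to 0.25). The main test used no pairing, and pairs in those groups stay possible. A count-based test was not run.

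Limma and camera were tested on simulated data with the same group sizes. For the peak comparison 92 of 100 genes changed by 1 on the log2 scale were recovered, and 100 of 100 changed by 2, with 9 false calls. For the change from peak to late resolution 76 and 96 of 100 were recovered, with 5 false calls. With no simulated difference between sex labels at peak there were 0 false calls by limma. Of the lists, 2 of 2 that were moved were called by camera and 0 of 33 that were not. Without correlation between genes this does not show how often real genes or lists are called falsely. Camera with an estimated correlation and fry were not simulated. Sex labels were checked against Xist and Y-linked transcripts. No library was moved to another group.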

Results

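The series profiled whole liver from wild-type mice fed a Lieber-DeCarli liquid diet, a standard model of alcohol-associated liver disease in which ethanol replaces part of the carbohydrate calories. Transcript levels were measured by bulk RNA sequencing in 45 libraries at 3 stages. The peak stage followed 6 weeks of control or ethanol diet, early resolution followed a further 3 days on control diet, and late resolution followed 2 weeks on control diet. Stage, diet and sex labels defined 12 groups, 9 with 4 libraries and 3 with 3 libraries. The groups of 3 were the ethanol-labelled females at early resolution and the ethanol-labelled females and males at late resolution. Peak held 16 libraries, early resolution 15 and late resolution 14. Libraries are named by their labels, as in peak control female 1. Values are in TPM (transcript abundance scaled to a fixed total in each library), so sequencing depth is unknown. Between 15093 and 16402 genes were above 0 in a library, and 11244 genes were tested. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries.

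The transcripts that mark sex in mouse liver followed the diet label. Xist, the noncoding RNA that silences an X chromosome in female cells, lies on chromosome X (mm10, 103460366 to 103483254, annotated as a long intergenic noncoding RNA gene). Eif2s3y and Ddx3y, which encode a translation initiation factor subunit and an RNA helicase, lie on chromosome Y (1010543 to 1028847, and 1260771 to 1286629). In 21 of 21 ethanol-labelled libraries Xist stood between 13.68 and 51.82 TPM and Eif2s3y at or under 0.04 TPM. In 23 of 24 control-labelled libraries Eif2s3y stood between 7.83 and 12.65 TPM and Xist at or under 0.35 TPM. The exception, late control female 1, had 39.54 TPM of Xist and Eif2s3y listed at 0. At peak, Xist was 0.107 ± 0.162 TPM (SD, n = 4) in control-labelled females and 23.3 ± 4.16 TPM (SD, n = 4) in ethanol-labelled males. Ddx3y was 3.32 ± 0.785 TPM (SD, n = 4) in control-labelled females and 0.000642 ± 0.000745 TPM (SD, n = 4) in ethanol-labelled males. These transcripts disagreed with the sex label in 22 of 45 libraries, 11 labelled female and 11 labelled male. The groups were kept as labelled, and every direction given for ethanol or for sex refers to libraries labelled that way.

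**Figure D1:**
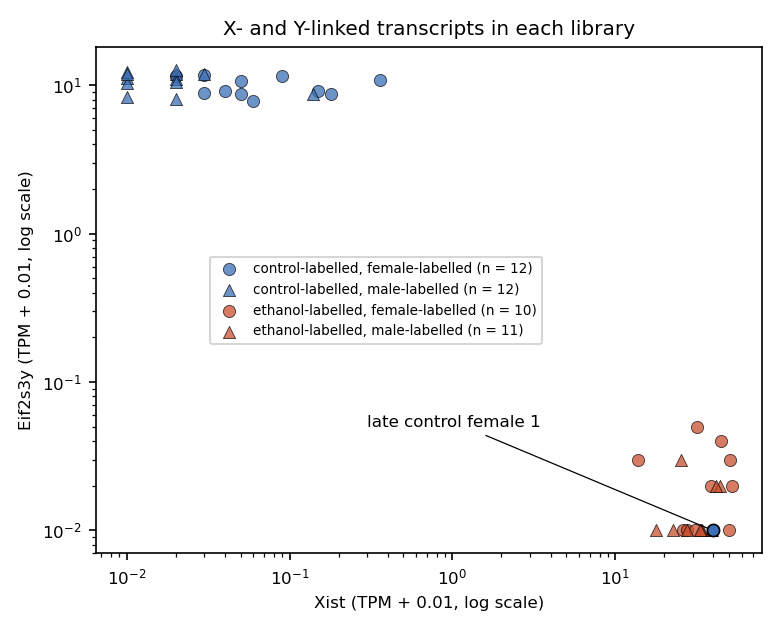
Xist against Eif2s3y in each of the 45 libraries, in TPM with 0.01 added, on log axes; blue marks control-labelled and orange ethanol-labelled libraries, circles female-labelled and triangles male-labelled. The 21 ethanol-labelled libraries have Xist of at least 13.68 TPM whatever their sex label, and late control female 1 lies among them.

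At peak, after 6 weeks of either diet, large differences between ethanol-labelled and control-labelled livers lay in genes known to differ between male and female liver. All 20 tested members of the list of female-biased liver genes were higher in ethanol-labelled livers and 18 of 20 male-biased genes were lower, or 20 and 19 when adjusted over the list alone. With camera and an estimated correlation the adjusted p was 0.041 for the first list and 0.0093 for the other. Cyp2a4, a steroid-hydroxylating cytochrome P450 (chromosome 7, 26307169 to 26315088), stood at 2430 ± 1320 TPM (SD, n = 4) in ethanol-labelled females and 31.8 ± 34.6 TPM (SD, n = 4) in control-labelled females. In male-labelled livers it stood at 2440 ± 684 TPM (SD, n = 4) with ethanol and 3.22 ± 4.95 TPM (SD, n = 4) with control. Its log2 difference was 8.36 ± 0.79 (SE, adjusted p = 2.4e-10), in the same direction in 8 of 8 ethanol-labelled libraries. The sulfotransferase Sult2a1 was higher by 8.34 ± 0.80 (SE, adjusted p = 3.9e-10). The major urinary protein gene Mup7 (chromosome 4, 60066469 to 60070475) fell by 10.99 ± 0.99 (SE, adjusted p = 8.3e-11) in the ethanol-labelled livers, from 26500 ± 3630 TPM to 6.68 ± 5.56 TPM (SD, n = 4 each) in those labelled male. Cyp4a12a, a fatty acid hydroxylase (chromosome 4, 115299046 to 115332815), differed by -8.52 ± 0.66 (SE, adjusted p = 4.1e-12). The elongase Elovl3 (chromosome 19, 46131897 to 46135694), which makes very long chain fatty acids, differed by -5.51 ± 0.36 (SE, adjusted p = 2.5e-13). Each of these differences was in 8 of 8 ethanol-labelled libraries. Values of Mup7, Cyp2a4, Sult2a1 and Cyp4a12a are uncertain because each has near-identical copies that can share reads.

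**Figure D2:**
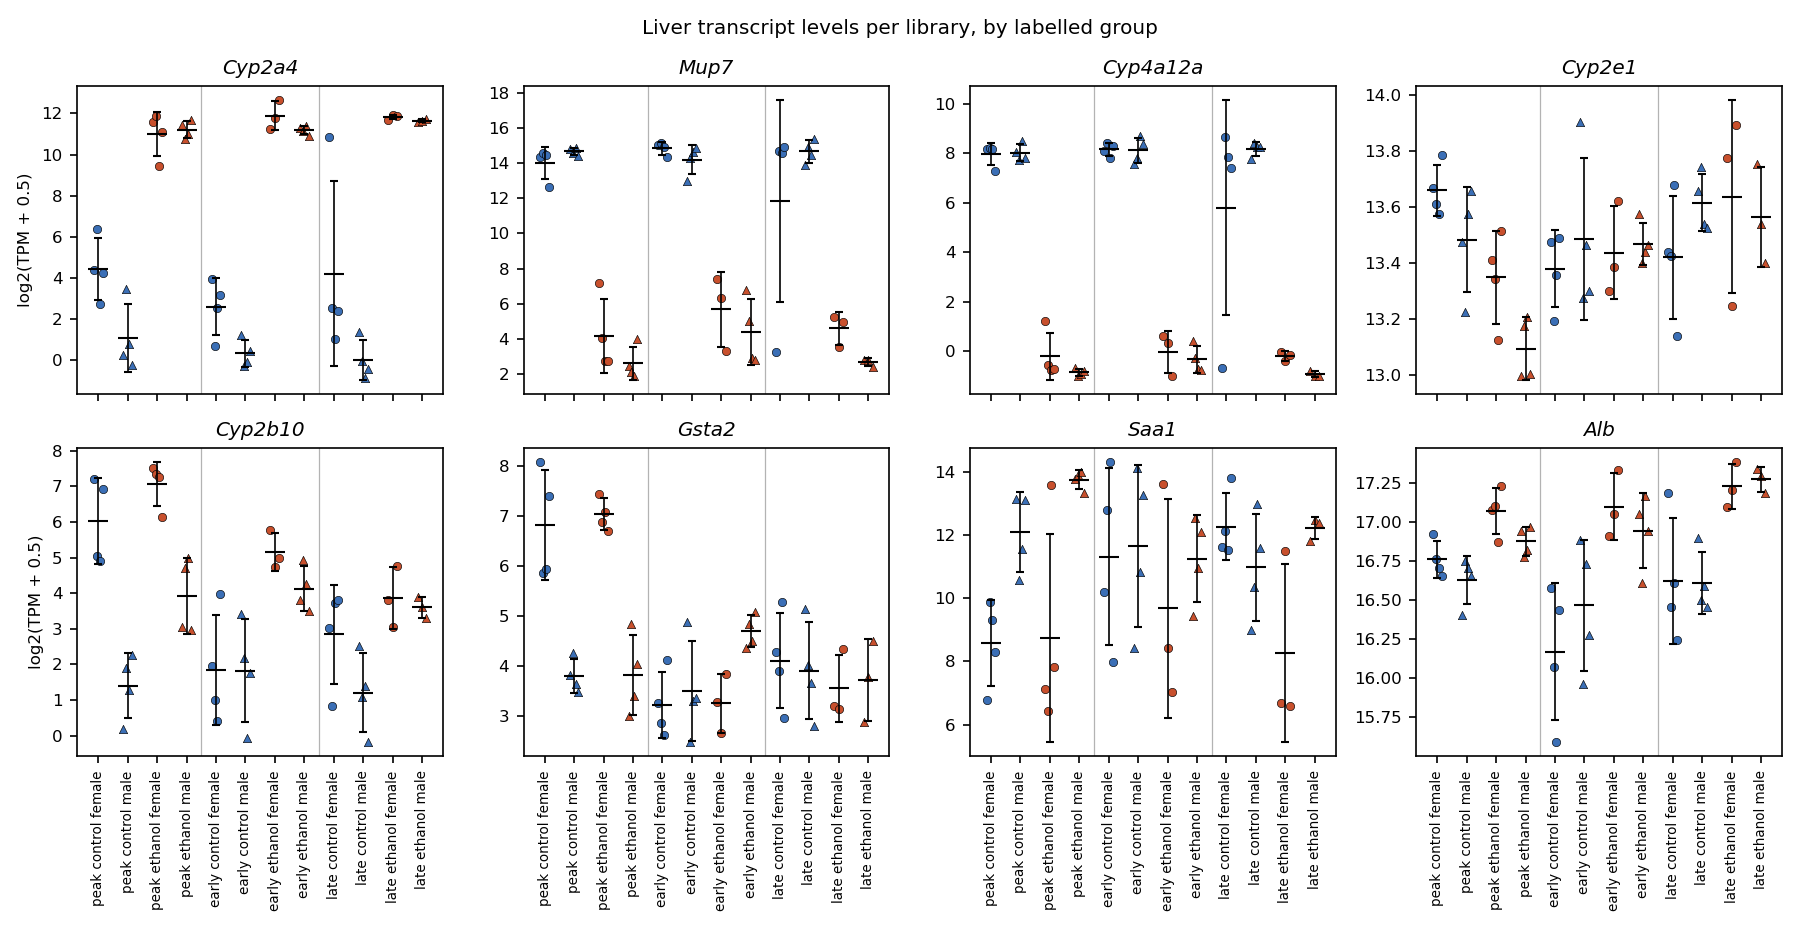
Levels of Cyp2a4, Mup7, Cyp4a12a, Cyp2e1, Cyp2b10, Gsta2, Saa1 and Alb in each library as log2(TPM + 0.5), by stage; blue marks control-labelled and orange ethanol-labelled libraries, circles female-labelled and triangles male-labelled, and bars give the group mean ± SD. Cyp2a4 and Mup7 separate by diet label at each stage except in late control female 1, while Gsta2 and Cyp2b10 differ by sex label at peak.

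Genes of ethanol oxidation moved in both directions at peak. Of 11 tested, 3 were higher (Adh1, Adh7 and Aldh1b1) and 6 lower (adjusted p = 0.7 with an estimated correlation). Cyp2e1, the cytochrome P450 that oxidises ethanol and is a common marker of its intake (chromosome 7, 140763739 to 140774987), was lower by -0.35 ± 0.10 (SE, adjusted p = 0.0065) in 8 of 8 ethanol-labelled libraries. The call was lost with quantile normalization (-0.08, adjusted p = 0.72). Adh1, an alcohol dehydrogenase (chromosome 3, 138260991 to 138290698), was higher by 0.54 ± 0.12 (SE, adjusted p = 0.0013) in 7 of 8. The retinaldehyde-oxidising Aldh1a1 and the dehydrogenase Adh4 were lower by -1.04 ± 0.17 (SE, adjusted p = 1.5e-05) and -1.09 ± 0.21 (SE, adjusted p = 0.00023), each in 8 of 8. For the mitochondrial aldehyde dehydrogenase Aldh2 (chromosome 5, 121566027 to 121593824) the difference was 0.10 ± 0.10 (SE, adjusted p = 0.53), and for Alb, which encodes serum albumin (chromosome 5, 90460897 to 90476602), 0.28 ± 0.13 (SE, adjusted p = 0.11).

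With an estimated correlation none of the endothelial, matrix, stellate cell and cytokine lists passed at peak (adjusted p = 0.49 for the first and 0.38 for the others). All 12 endothelial markers were higher in ethanol-labelled livers, among them the junction gene Cdh5 (1.04 ± 0.16, SE, adjusted p = 8.6e-06) and Pecam1 (0.98 ± 0.18, SE, adjusted p = 0.00011), each in 8 of 8 libraries. Of 18 extracellular matrix and fibrosis genes 13 were higher, 18 when adjusted over the list alone, and of 11 stellate cell markers 9, or 10 over the list alone. The proteoglycan gene Dcn differed by 0.85 ± 0.18 (SE, adjusted p = 0.00047) and the cytokine gene Tgfb1 by 0.64 ± 0.13 (SE, adjusted p = 0.00024), each in 8 of 8. Among 16 cytokine and chemokine genes 8 were higher, including the interleukin-1 antagonist gene Il1rn (1.87 ± 0.22, SE, adjusted p = 2.8e-08) and the monocyte attractant gene Ccl2 (0.98 ± 0.17, SE, adjusted p = 4.4e-05). Of 17 integrated stress response genes 7 were higher and 1 lower, or 8 and 1 over the list alone (adjusted p = 0.23 with an estimated correlation). The lower member was Asns, an asparagine synthetase, at -3.12 ± 0.63 (SE, adjusted p = 0.00031). Of 18 complement genes 6 were lower and 2 higher (C3 and Mbl2), or 8 and 4 over the list alone (adjusted p = 0.54 with an estimated correlation). C6, a component of the membrane attack complex, fell by 3.83 ± 0.32 (SE, adjusted p = 2.4e-11) in 8 of 8. Of 20 bile acid genes 5 were lower, among them the hydroxylases Cyp7b1 (-3.43 ± 0.40, SE, adjusted p = 3.6e-08) and Cyp8b1 (-2.02 ± 0.37, SE, adjusted p = 8.8e-05), and 2 were higher, or 5 and 3 over the list alone (adjusted p = 0.61 with an estimated correlation). Of 24 fatty acid oxidation genes 9 were higher and 1 (Angptl4) lower, or 10 and 1 over the list alone (adjusted p = 0.76 with an estimated correlation). Pdk4, a kinase that limits glucose oxidation, was higher by 2.29 ± 0.38 (SE, adjusted p = 2.7e-05).

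In all, 3049 of 11244 genes differed by diet label at peak by limma, 1946 higher and 1103 lower, and 444 by at least 1 in log2. The share higher was 63.8% as deposited, 48.1% of 4005 with median-of-ratios scaling and 45.9% of 3927 with quantile normalization. Camera called 15 lists at a correlation of 0.01 and 2 with it estimated.

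**Figure D3:**
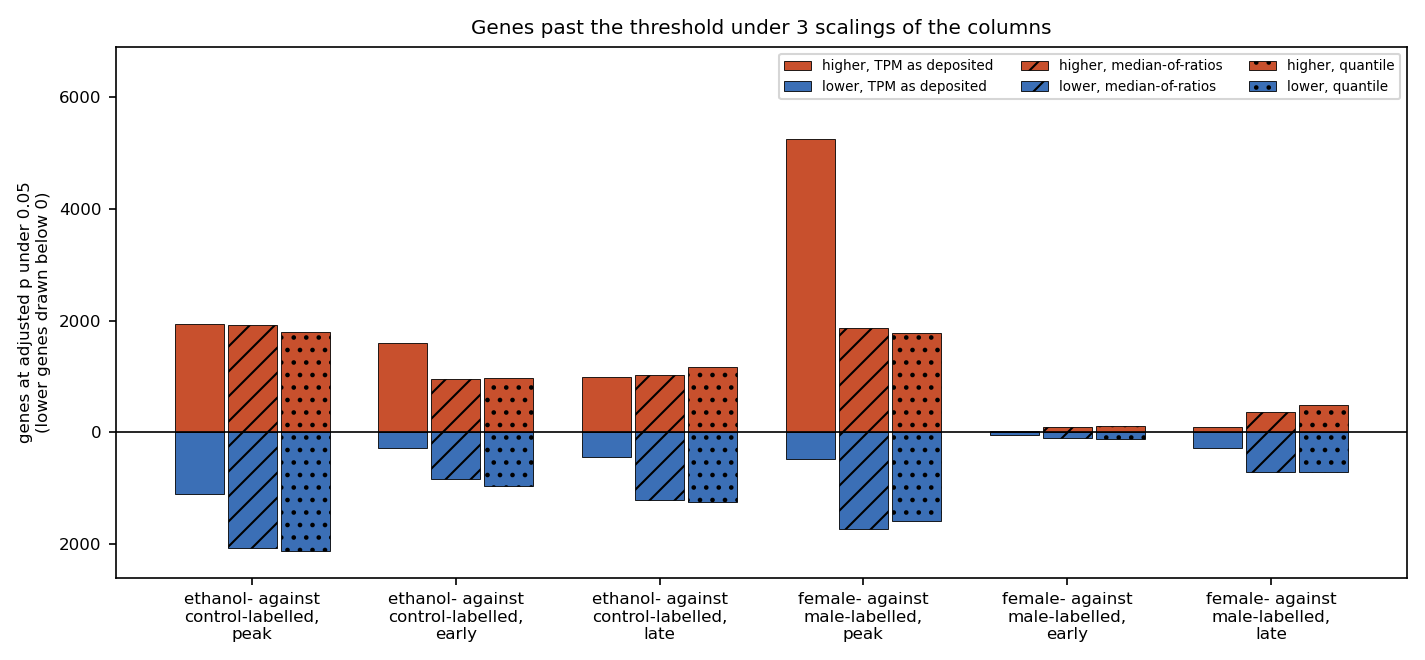
Number of genes higher and lower at adjusted p under 0.05 in 6 comparisons, under the deposited scaling, median-of-ratios scaling and quantile normalization. Of the genes that differ between female-labelled and male-labelled livers at peak, 91.6% are higher as deposited and 51.9% with median-of-ratios scaling.

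Early resolution followed 3 days on control diet. The median of all genes lay 0.13 higher on the log2 scale in ethanol-labelled livers, so values here are relative to that shift, with median-of-ratios scaling. All 20 female-biased liver genes were higher and 19 of 20 male-biased genes lower, the same numbers over the list alone (adjusted p = 0.0033 and 0.00016 with an estimated correlation). Cyp2a4 differed by 9.93 ± 0.80 (SE, adjusted p = 2.8e-11) and Mup7 by -9.68 ± 1.06 (SE, adjusted p = 1.3e-08), each in 7 of 7 ethanol-labelled libraries. Of 19 xenobiotic response genes 11 were higher and 2 lower, among them the P450 Cyp2c37 at 1.61 ± 0.22 (SE, adjusted p = 1.2e-06); as deposited the numbers were 11 and 1, or 14 and 2 over the list alone (adjusted p = 0.2 with an estimated correlation). Of 24 fatty acid oxidation genes 10 were higher, against 12 as deposited and 15 over the list alone (adjusted p = 0.45 with an estimated correlation). The fatty acid hydroxylase Cyp4a10 differed by 1.79 ± 0.31 (SE, adjusted p = 6.7e-05) and the acyl-CoA dehydrogenase Acadl by 0.54 ± 0.09 (SE, adjusted p = 2.1e-05). Resident macrophage markers were higher in 8 of 14, against 10 as deposited and 11 over the list alone (adjusted p = 0.47 with an estimated correlation). They included the complement gene C1qc (0.72 ± 0.15, SE, adjusted p = 0.00098) and the complement receptor gene Vsig4 (0.78 ± 0.19, SE, adjusted p = 0.0048). Of 10 T and NK cell markers 7 were higher and 1 lower, against 8 and 1 as deposited and 9 and 1 over the list alone (adjusted p = 0.48 with an estimated correlation). The granzyme gene Gzmb was higher by 0.83 ± 0.18 (SE, adjusted p = 0.0016), and the T cell coreceptor gene Cd4 was the lower member at -1.30 ± 0.19 (SE, adjusted p = 2.7e-06).

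Of 19 endoplasmic reticulum chaperone genes 7 were lower at early resolution after the same scaling, against 4 as deposited and 5 over the list alone (adjusted p = 0.2 with an estimated correlation). The protein disulfide isomerases Pdia6 and Pdia3 differed by -0.76 ± 0.14 (SE, adjusted p = 2e-04) and -0.63 ± 0.13 (SE, adjusted p = 0.00092), each in 7 of 7 libraries. Of 18 complement genes 7 were lower and 1 (Mbl2) higher, against 5 and 1 as deposited and over the list alone (adjusted p = 0.2 with an estimated correlation), with C6 at -4.12 ± 0.36 (SE, adjusted p = 7.1e-11). Among 14 proliferation genes 6 were higher, the same number as deposited and 11 over the list alone (adjusted p = 0.5 with an estimated correlation), and the cyclin gene Ccnd1 differed by 2.03 ± 0.23 (SE, adjusted p = 2.1e-08). Ribosomal protein genes, 13 of 22 higher as deposited and 17 over the list alone (adjusted p = 0.59 with an estimated correlation), gave none after median-of-ratios scaling. The Adh1 difference was 0.64 ± 0.10 (SE, adjusted p = 2.6e-05) and the Alb difference 0.55 ± 0.12 (SE, adjusted p = 0.00084), both in 7 of 7, though quantile normalization gives Alb, the top transcript, a value of 0. Cyp2e1 changed sign with the scaling, at 0.02 ± 0.10 (SE, adjusted p = 0.93) as deposited, -0.13 (adjusted p = 0.41) with median-of-ratios scaling and 0.50 (adjusted p = 0.029) with quantile normalization. As deposited 1880 genes differed by limma, 1603 higher and 277 lower. With median-of-ratios scaling there were 1789, of which 53% were higher, against 85.3% as deposited. The count was 3016 without early ethanol female 1 and 1123 without early ethanol female 2.

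At late resolution, after 2 weeks on control diet, the sex-biased genes still separated the libraries by diet label. All 20 female-biased genes were higher and 18 of 20 male-biased genes lower, or 20 and 19 over the list alone (adjusted p = 0.0051 and 0.0037 with an estimated correlation). Cyp2a4 differed by 9.63 ± 0.85 (SE, adjusted p = 3.2e-10) and Mup7 by -9.67 ± 1.07 (SE, adjusted p = 2e-08), each in 6 of 6 ethanol-labelled libraries. The control-labelled mean holds late control female 1, and without it these differences were 10.74 and -11.10. Each immune and ribosomal list below had adjusted p = 0.48 with an estimated correlation. Of 22 interferon response genes 11 were higher in ethanol-labelled livers, or 12 over the list alone, including the antiviral genes Oasl2 (0.93 ± 0.20, SE, adjusted p = 0.0015) and Zbp1, a nucleic acid sensor (1.13 ± 0.21, SE, adjusted p = 0.00024). Of 10 T and NK cell markers 8 were higher, or 9 over the list alone, such as the T cell receptor component Cd3d at 0.88 ± 0.19 (SE, adjusted p = 0.0018). The B cell receptor components Cd79a (1.89 ± 0.33, SE, adjusted p = 1e-04) and Cd79b (1.34 ± 0.29, SE, adjusted p = 0.0019) were higher. Resident macrophage markers were higher in 6 of 14, or 9 over the list alone, with C1qa at 0.85 ± 0.19 (SE, adjusted p = 0.0019). Ribosomal protein genes were higher in 18 of 22, or 20 over the list alone, but in 6 with median-of-ratios scaling. Each difference of a gene named in this paragraph held its direction in 6 of 6 ethanol-labelled libraries.

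Of 14 gluconeogenesis and insulin response genes 2 were lower at late resolution, or 3 over the list alone (adjusted p = 0.48 with an estimated correlation). They were Pfkfb3, which regulates glycolysis, at -1.77 ± 0.35 (SE, adjusted p = 0.00066) and the tyrosine aminotransferase gene Tat at -1.14 ± 0.28 (SE, adjusted p = 0.0061). Adh1 stayed higher in ethanol-labelled livers by 0.67 ± 0.13 (SE, adjusted p = 0.00073) in 6 of 6. Alb differed by 0.63 ± 0.14 (SE, adjusted p = 0.0027), a call lost without the low-value filter (adjusted p = 0.093), with the stage alone (adjusted p = 0.061), with the replicate block (0.54, adjusted p = 0.051) and, by construction, with quantile normalization. Cyp2e1 differed by 0.08 ± 0.10 (SE, adjusted p = 0.63) and by -0.10 with array weights. As deposited 1440 genes differed, 992 higher and 448 lower, a share of 68.9% higher against 46% of 2250 with median-of-ratios scaling. The replicate block gave 580 genes and the fit to late libraries alone 727. Without late control female 1, whose sex-chromosome transcripts stand apart from its group, the count was 2098.

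Large ethanol-labelled differences recurred between stages, while the ranks of all genes were less alike. Across the 11244 genes, which are not independent replicates, log2 differences correlated with Pearson r = 0.823 between peak and early, 0.73 between peak and late and 0.91 between early and late resolution. Spearman rho, which gives the largest differences less weight, was 0.49, 0.281 and 0.755. Peak and late shared 461 higher and 257 lower genes, where independent lists would share 171.7 and 43.9, and 7 genes had opposite directions. Early and late shared 743 higher and 212 lower genes, where independence gives 141.4 and 11. Stages share no library. Within female-labelled livers 748, 441 and 277 genes differed at peak, early and late resolution, and within male-labelled livers 2635, 943 and 724. The shares that were higher in female-labelled livers were 75.7%, 62.6% and 57% as deposited and 46.3% of 834, 43% of 586 and 40% of 430 with median-of-ratios scaling. In male-labelled livers at early resolution the share was 84%, against 63% of 930. The median of all genes was shifted by 0.15 in females at peak, 0.16 in males at early and 0.12 in females at late resolution. Without peak control female 1 or peak ethanol female 1 the female count at peak was 450 or 426. Without early ethanol female 2 the female count at early resolution was 287, and the male one was 448, 515 and 544 without early control male 2, early control male 4 and early ethanol male 1. At late resolution the female count ranged from 122 to 991 and the male count from 318 to 738 over the single omissions, moving by more than 1.5 times in 5 and 6 of 7.

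Because the sex-chromosome transcripts followed the diet label, female-labelled and male-labelled livers were also compared at each stage, averaged over the diet labels, a comparison chosen after that was seen. At peak the median of all genes lay 0.29 higher in female-labelled livers, so values are relative to that shift, with median-of-ratios scaling. Of 19 xenobiotic response genes 13 were higher in female-labelled livers and 1 lower, against 15 and 0 as deposited and over the list alone (adjusted p = 0.32 with an estimated correlation). The phenobarbital-inducible P450 Cyp2b10 (chromosome 7, 25897620 to 25926624) differed by 3.57 ± 0.53 (SE, adjusted p = 9.7e-06). As deposited it stood at 82.3 ± 60 TPM in control-labelled females, 141 ± 49.1 in ethanol-labelled females, 2.51 ± 1.57 in control-labelled males and 17.9 ± 12.2 in ethanol-labelled males (SD, n = 4 each). Of 21 antioxidant and glutathione genes 13 were higher and 2 lower, against 15 and 1 as deposited and 17 and 1 over the list alone (adjusted p = 0.32 with an estimated correlation). The glutathione transferase gene Gsta2 (chromosome 9, 78331018 to 78355788) differed by 2.78 ± 0.35 (SE, adjusted p = 7.8e-07) and Gclc, a subunit of the rate-limiting enzyme of glutathione synthesis, by 1.45 ± 0.16 (SE, adjusted p = 1.4e-07). The glucuronosyltransferase Ugt1a9 differed by 2.29 ± 0.30 (SE, adjusted p = 1.7e-06), the keratin gene Krt23 by 2.41 ± 0.33 (SE, adjusted p = 2.7e-06) and the stress cytokine gene Gdf15 by 1.82 ± 0.41 (SE, adjusted p = 0.0012). The first 5 of these genes were higher in 8 of 8 female-labelled libraries and Gdf15 in 7 of 8. Gsta2 and Cyp2b10 have close copies, so their values are uncertain.

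Of 22 acute phase genes 17 were lower in female-labelled livers at peak after the same scaling, against 16 lower and 1 higher as deposited and 17 and 1 over the list alone (adjusted p = 0.17 with an estimated correlation). Saa1, which encodes an amyloid A protein carried on plasma lipoproteins (chromosome 7, 46740497 to 46742980; near-identical to Saa2), differed by -4.60 ± 1.05 (SE, adjusted p = 0.0013). The iron-siderophore binder Lcn2 (chromosome 2, 32384633 to 32388252) differed by -4.62 ± 1.01 (SE, adjusted p = 0.00091). Peak ethanol female 3 stood apart from the other 3 of its group, with Saa1 at 12300 TPM against 86.3 to 227 and Lcn2 at 3940 TPM against 45.2 to 82.2. As deposited the differences were -4.26 and -4.28, and -5.07 and -5.04 without it. Of 8 neutrophil markers 7 were lower, against 6 as deposited and over the list alone (adjusted p = 0.087 with an estimated correlation). Lipogenesis genes were lower in 11 of 20 and higher in 1, against 7 and 4 as deposited and 8 and 4 over the list alone (adjusted p = 0.32 with an estimated correlation), with the lipogenic regulator Thrsp at -2.74 ± 0.31 (SE, adjusted p = 2.1e-07). Of 24 cholesterol synthesis genes 11 were lower, against 6 lower and 2 higher as deposited and 5 and 2 over the list alone (adjusted p = 0.39 with an estimated correlation). The squalene epoxidase Sqle differed by -1.68 ± 0.24 (SE, adjusted p = 6e-06). Chaperone genes were lower in 11 of 19, against 3 lower and 1 higher as deposited and over the list alone (adjusted p = 0.32 with an estimated correlation). The fatty acid binding protein gene Fabp5 (chromosome 3, 10012548 to 10016607) differed by -2.89 ± 0.36 (SE, adjusted p = 7.7e-07). Each gene named here was lower in 8 of 8 female-labelled libraries. Of the sex-biased lists, 3 female-biased genes were higher and 3 lower, and 2 male-biased genes were higher and 2 lower, of 20 each.

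As deposited, 5729 genes differed between female-labelled and male-labelled livers at peak, 5250 higher and 479 lower. With median-of-ratios scaling there were 3587, and the share that was higher was 51.9% against 91.6% as deposited. Of the genes called, 2340 were called in the same direction under both scalings and 4 in opposite directions. The count differed between the diet labels, with 326 genes in control-labelled and 5559 in ethanol-labelled livers, or 341 and 3551 with median-of-ratios scaling and 4789 and 6901 with array weights. A direct test of that gap is the sex difference in the ethanol-labelled effect, which called 18 genes as deposited, 47 with median-of-ratios scaling, 2141 with array weights and 4 to 134 over single omissions. Without peak control female 2, 3 or 4 the control-labelled count was 137, 145 or 198, and without peak control male 1, 2 or 3 it was 120, 202 or 213. Adh1 was higher in female-labelled livers by 0.64 ± 0.12 (SE, adjusted p = 0.00018) as deposited and by 0.30 ± 0.10 (SE, adjusted p = 0.019) with median-of-ratios scaling. Aldh2 was higher by 0.44 ± 0.10 (SE, adjusted p = 0.001), a call lost with that scaling (0.11, adjusted p = 0.38). Cyp2e1 changed sign, from 0.21 (adjusted p = 0.063) as deposited to -0.12 (adjusted p = 0.35), but passed at 0.49 (adjusted p = 0.016) with quantile normalization. Cyp2e1 also passed without peak ethanol female 3 (0.25, adjusted p = 0.033), without peak control male 4 (0.24, adjusted p = 0.046), with array weights (0.20, adjusted p = 0.027) and with the stage alone (0.21, adjusted p = 0.042). Alb changed sign from 0.16 (adjusted p = 0.3) to -0.17 (adjusted p = 0.23).

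At early and late resolution the sex labels separated fewer genes. In the early stage 67 differed as deposited, 25 higher and 42 lower in female-labelled livers (37.3% higher, against 49.5% of 202 with median-of-ratios scaling). Of 18 one-carbon and methionine genes 2 were lower, Bhmt and Dmgdh, or 8 over the list alone (adjusted p = 0.36 with an estimated correlation). Dmgdh lost its call in 5 of 15 fits with 1 library left out (highest adjusted p = 0.13). Bhmt, which remethylates homocysteine, differed by -1.75 ± 0.26 (SE, adjusted p = 0.00047) in 6 of 7 female-labelled libraries. Outside that list Gldc, which cleaves glycine, differed by -1 ± 0.17 (SE, adjusted p = 0.0014) in 7 of 7. The clock gene Cry1 differed by -0.71 ± 0.11 (SE, adjusted p = 0.00047) and the pentose phosphate enzyme gene G6pdx by 1.00 ± 0.16 (SE, adjusted p = 0.00095), each in 7 of 7. In the fit to early libraries alone Gldc and G6pdx had adjusted p = 0.062, at the same log2 values, and their alternatives are ranged in the closing section. At late resolution 365 genes differed, 88 higher and 277 lower (24.1% higher, against 33.6% of 1071). Of 14 gluconeogenesis and insulin response genes 5 were lower (Pck1, G6pc, Tat, Igfbp1 and Foxo1), or 8 over the list alone (adjusted p = 0.97 with an estimated correlation). Pck1, an enzyme of gluconeogenesis, differed by -1 ± 0.19 (SE, adjusted p = 0.005). Tat differed by -1.46 ± 0.28 (SE, adjusted p = 0.0062) and the glucocorticoid-induced Tsc22d3 by -1.58 ± 0.30 (SE, adjusted p = 0.0048). Of 19 chaperone genes 5 were lower (Hspa5, Dnajc3, Herpud1, Edem1 and Canx), or 10 over the list alone (adjusted p = 0.97 with an estimated correlation), with Herpud1 at -0.71 ± 0.13 (SE, adjusted p = 0.0046). These 4 genes were lower in 7 of 7 female-labelled libraries. G6pc and Igfbp1 lost their calls in 3 of 14 single omissions each, Edem1 in 5. Over single omissions the early count ranged from 16 (without early ethanol female 2) to 206 (without early ethanol female 3) and moved by more than 1.5 times in 10 of 15 fits. The late count ranged from 25 (without late ethanol female 1) to 1853 (without late ethanol female 3) and moved so in 12 of 14.

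The difference between sex labels changed from peak to each later stage. Relative to all-gene shifts of -0.32 and -0.34, Fabp5 changed by 4.41 ± 0.52 (SE, adjusted p = 1.4e-06) from peak to early and by 3.25 ± 0.53 (SE, adjusted p = 0.00029) from peak to late. Gsta2 changed by -3.61 ± 0.51 (SE, adjusted p = 2e-05) and -2.71 ± 0.52 (SE, adjusted p = 0.00084), and Ugt1a9 by -2.65 ± 0.43 (SE, adjusted p = 0.00013) and -2.82 ± 0.44 (SE, adjusted p = 0.00019). Socs3, a feedback inhibitor of cytokine signalling, changed by 3.47 ± 0.79 (SE, adjusted p = 0.0033) to late resolution. As deposited 3582 genes changed from peak to early, 257 upward and 3325 downward, and 4105 from peak to late, 213 and 3892. The share upward was 7.2% and 5.2%, against 44.4% of 1871 and 42.9% of 2312 with median-of-ratios scaling. Without early ethanol female 1 the count to early resolution was 1803.

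As deposited the ethanol-labelled effect changed in fewer genes, but to late resolution not in all rescaled single omissions. From peak to late resolution 447 changed, 120 upward and 327 downward. Igfbp1, a gene induced by fasting, changed by -2.59 ± 0.67 (SE, adjusted p = 0.026), and Mcm10, a DNA replication factor gene, by 1.59 ± 0.39 (SE, adjusted p = 0.02). For Igfbp1 the value was -2.32 (adjusted p = 0.052) without peak ethanol female 3, -2.20 (adjusted p = 0.084) without late ethanol female 1 and -2.43 (adjusted p = 0.051) without late control male 3. With the replicate block no gene passed (adjusted p = 0.13 for Igfbp1 and 0.086 for Mcm10). The share upward was 26.8%, against 45.7% of 1369 with median-of-ratios scaling. Over single omissions the count ranged from 95 (without late ethanol female 1) to 1064 (without late ethanol female 3), moving by more than 1.5 times in 14 of 30 fits. From peak to early resolution limma called 0 genes, with 1879 at an unadjusted p under 0.05. There were 19 with median-of-ratios scaling, 13 with quantile normalization, 2171 with array weights, 1 without peak control female 4, 3 without peak ethanol male 3 and 1072 without early ethanol female 1. From early to late resolution limma called 0, with 354 at an unadjusted p under 0.05. There were 0 under both other scalings, 88 with array weights and 1 without early control female 1.

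Whether the ethanol-labelled effect depended on the sex label was tested as the male-labelled minus the female-labelled effect. At peak 18 genes passed, 10 positive and 8 negative. The all-gene shift was -0.20, and relative to it 47 genes passed. Tff3, a trefoil peptide of mucosal repair, had a difference of -4.45 ± 0.90 (SE, adjusted p = 0.012). The kinase-like gene Adck5 had -1.74 ± 0.29 (SE, adjusted p = 0.0043), Coq8b, which takes part in coenzyme Q synthesis, 2.15 ± 0.41 (SE, adjusted p = 0.0089), and the carbonic anhydrase gene Car14 -1.64 ± 0.37 (SE, adjusted p = 0.029). As deposited, Tff3 lost its call without peak control female 3 (-4.29, adjusted p = 0.052), peak control male 2 (-4.00, adjusted p = 0.06) or peak control male 3 (-4.18, adjusted p = 0.054), and with a pseudocount of 0.1 (-3.91, adjusted p = 0.14). Car14 lost it without peak ethanol male 1 (-1.71, adjusted p = 0.061) and with the block (adjusted p = 0.055). The count ranged from 4 to 134 over single omissions and moved by more than 1.5 times in 11 of 16 fits. At early resolution 1 gene passed, the sulfotransferase-family gene Sult3a2 (2.27 ± 0.42, SE, adjusted p = 0.044), named after its value was seen. It was lost in 14 of 15 single omissions, and 0 genes passed with median-of-ratios scaling or quantile normalization, with 516 at an unadjusted p under 0.05 as deposited. At late resolution 5 passed and the all-gene shift was -0.14. Relative to it G6pc, which releases glucose from the liver, had 3.21 ± 0.53 (SE, adjusted p = 0.0058), Errfi1, an inhibitor of the epidermal growth factor receptor, 1.85 ± 0.32 (SE, adjusted p = 0.0088), and the glycine transporter gene Slc6a9 1.49 ± 0.29 (SE, adjusted p = 0.016). The other 2, named after their values were seen, were D17H6S56E-5 at 2.46 ± 0.44 (SE, adjusted p = 0.011) and 9430037G07Rik at -1.41 ± 0.32 (SE, adjusted p = 0.051). The count was 0 with the block, in the fit to late libraries alone and without late control female 1, and 10 without late control female 3.

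Among control-labelled livers, male-labelled were compared with female-labelled across the 3 stages, 12 libraries each, as a check of the sex label. None of 3 sex-chromosome transcripts passed as deposited. The differences were -0.67 ± 0.37 for Xist (SE, adjusted p = 0.34), 0.51 ± 0.20 for Ddx3y (SE, adjusted p = 0.18) and 0.47 ± 0.26 for Eif2s3y (SE, adjusted p = 0.33). Ddx3y passed with array weights (0.45, adjusted p = 0.04) and without late control female 4 (0.62, adjusted p = 0.042). Cyp2a4 was lower in male-labelled controls by -3.27 ± 0.64 (SE, adjusted p = 0.0062) and Cyp2b10 by -2.09 ± 0.42 (SE, adjusted p = 0.0072), while Tff3 was higher by 2.28 ± 0.35 (SE, adjusted p = 0.00035). Late control female 1 is among the female-labelled controls. Without it Cyp2a4 differed by -2.53 (adjusted p = 0.00054), Xist by -0.15 (adjusted p = 0.47), Ddx3y by 0.27 (adjusted p = 0.24) and Eif2s3y by 0.11 (adjusted p = 0.38). In all 150 genes differed, 40 higher and 110 lower (26.7% higher, against 41.9% of 551 with median-of-ratios scaling). The count ranged from 58 (without late control male 3) to 835 (without late control female 4) and moved by more than 1.5 times in 10 of 24 single omissions.

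Control-labelled livers also differed between stages, the background for every comparison across them. From peak to early resolution the neutrophil alarmin genes S100a8 and S100a9 changed by -2.73 ± 0.51 (SE, adjusted p = 0.0039) and -2.62 ± 0.47 (SE, adjusted p = 0.0027), and the glutathione transferase Gstm3 by -1.73 ± 0.28 (SE, adjusted p = 0.0016). In all 82 genes changed, 39 upward and 43 downward (47.6% upward, against 34.9% of 252 with median-of-ratios scaling). From peak to late resolution the all-gene shift was 0.14, and relative to it G6pc changed by 1.26 ± 0.24 (SE, adjusted p = 0.0068) and the glutathione transferase Gstm1 by -1.23 ± 0.18 (SE, adjusted p = 0.00079). As deposited G6pc had 1.42 ± 0.28 (SE, adjusted p = 0.012), and without peak control male 1 its value was 1.33 (adjusted p = 0.053). There were 76 genes as deposited, 68 upward and 8 downward (89.5% upward, against 35.7% of 112). Over single omissions the first count ranged from 26 (without early control male 4) to 119 (without early control male 1) and moved by more than 1.5 times in 10 of 16 fits. The other ranged from 7 (without peak control male 1) to 904 (without late control female 3) and moved so in 14 of 16.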

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

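Of the tests below, those of a diet effect on the sex-chromosome transcripts, of a mixture of 2 livers, of both count ratios with rescaling and 1 library left out, of a difference between animals of 1 sex and of the scaling, and all comparisons of female-labelled with male-labelled libraries, were chosen only after the result was seen. The other tests were planned, or written down before the value they measure was seen.

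The sex-chromosome transcripts followed the diet label in 44 of 45 libraries. An effect of diet on these transcripts is argued against by Xist of at most 0.349 TPM in the 4 female-labelled control libraries at peak, and a Y-linked sum of at most 0.016 TPM in the male-labelled ethanol libraries at peak. Wrong sex labels with right diet labels and exchanged sex and diet codes cannot be told apart, since the counts that would separate them depend on scaling and single libraries. For the change from peak to late resolution the sex label called 9.18 times as many genes as the diet label (1.57 to 52.5 over 42 settings). This was 1.57 with quantile normalization, 1.69 with median-of-ratios scaling and 0.936 to 4.01 over 60 fits with either and 1 library left out. Between sex labels 15.7 times as many genes were called at peak as at late resolution (2.21 to 229 over 43 settings, and 1.36 to 35.1 over the same 60 fits). At peak the sex-label differences correlated across genes at r = 0.577 between control-labelled and ethanol-labelled libraries. This was above the bound written beforehand for exchanged codes, but wrong sex labels had none, so it does not separate them. Either way the difference between diet labels holds that of female minus male liver. Whether it also holds an effect of ethanol stays open, so no difference in the report can be assigned to ethanol.

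Late control female 1 stood apart from its group, with Xist at 39.5 TPM against at most 0.0751 TPM in the other 3. A mixture of 2 livers is argued against by Eif2s3y at 0% of the mean of the other 3, Mup7 at 0.0325% and Xist at 95.8% of the late ethanol-labelled mean. A difference between animals of 1 sex is argued against by this Xist level with a Y-linked sum of 0 TPM, where the other 3 had sums of 11.3 to 16.5 TPM, so at least 1 label in this group is wrong. For 1 wrongly labelled library, 75.8% of the 3049 genes called at peak lay nearer the late ethanol-labelled mean, but 41.3% to 61.1% did so in the other 3, so which label is wrong stays open. Without it the late count of ethanol against control was 2098 and that within female-labelled libraries 991, and no further biological explanation was tested.

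Most genes that differed between female-labelled and male-labelled libraries at peak were higher in the female-labelled, 91.6% as deposited. With median-of-ratios scaling 51.9% of 3587 genes were higher, and with quantile normalization 52.8% of 3356. Both scalings centre the all-gene difference, from 0.29 to 0.01 and 0, which sets a share near 50% whatever the cause, so the authors' scaling and a true shift in RNA cannot be told apart by it. Sequencing depth also stays open, as it is not given in the sources used here.

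Libraries far from their group were sought with 23 measures in the 9 groups of 4. Of 207 tests 27 passed, some in the same library, and the chance rate was not tested. The groups of 3 were not tested. Late control female 1 had 0.32% of TPM in Gm21320 against 1.53% to 1.72%, Cyp2b9 of 743 TPM against 1.8 to 19, and Cyp2a4 of 1860 TPM against 1.52 to 5.34. Peak control female 4 had 23.7% of TPM in the top 10 genes against 26.6% to 26.9%, Cyp4a12a of 155 TPM against 287 to 295, and Cyp2b9 of 180 TPM against 7.71 to 23.5. Peak ethanol female 1 had Eif2s3y of 0.0249 TPM against 0, Cyp4a12a of 1.81 TPM against 0.0923 to 0.177, and Mup7 of 143 TPM against 5.99 to 15.7. Peak control male 2 had Xist of 0.135 TPM against 0.00165 to 0.00925, Cyp2b9 of 6.29 TPM against 0.253 to 0.683, and Cyp2a4 of 10.6 TPM against 0.347 to 1.22. Peak control female 2 had Xist of 0.349 TPM against 0.00572 to 0.0414. In peak ethanol male 4 Eif2s3y was 0.0161 TPM against 0 and Mup7 15 TPM against 3.2 to 4.83. Late control male 1 had Cyp2b9 of 11.1 TPM against 0.383 to 0.758. Peak ethanol female 3 had Saa1 of 12300 TPM against 86.3 to 227 and Lcn2 of 3940 TPM against 45.2 to 82.2. Late control female 4 had Saa1 of 14100 TPM against 2950 to 4440 and Lcn2 of 6020 TPM against 255 to 1010. Early ethanol male 2 had 2.74% of TPM in Mir6236 against 1.06% to 1.27%, and early control female 4 had Cyp2a5 of 990 TPM against 480 to 550. Cyp7a1 was 0.754 TPM in peak control female 1 against 0.118 to 0.206, and 1.27 TPM in peak ethanol female 4 against 0.0178 to 0.224. Fos was 114 TPM in peak ethanol female 2 against 3.45 to 15.6, and 2.44 TPM in peak control male 3 against 0.956 to 1.14.

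The ethanol-labelled effect differed between sex labels, by a test of the difference, for 18 genes at peak, 1 at early and 5 at late resolution. At peak these included Tff3 (-4.38), Adck5 (-1.92), Coq8b (1.92), Car14 (-1.86), H3f3b (2.62) and Tubb6 (2.37). Over single omissions H3f3b lost its call in 11 of 16 fits and Tubb6 in 10. Early resolution gave Sult3a2 (2.27), and late resolution G6pc (3.05), Errfi1 (1.69), Slc6a9 (1.34), 9430037G07Rik (-1.56) and D17H6S56E-5 (2.33). Sult3a2 lost its call in 14 of 15 single omissions, and the late genes in 10, 8, 9, 13 and 7 of 14, in this order. From peak to late resolution the ethanol-labelled effect changed for 447 genes, among them Igfbp1 (-2.59), Mcm10 (1.59), Steap4 (-2.64), Hcar2 (-2.48), Pdk4 (-2), Nr1d1 (1.59) and Gmnn (1.57). Of these Steap4, Hcar2, Pdk4, Nr1d1 and Gmnn lost their calls in 15, 12, 18, 14 and 9 of 30 single omissions. The difference between sex labels changed for 3582 genes from peak to early and 4105 from peak to late resolution. To early resolution Fabp5 changed by 4.04, Gsta2 by -3.97, Cyp2b10 by -3.35, Ugt1a9 by -3.01 and S100a8 by 2.90 as deposited. To late resolution Ugt1a9 changed by -3.20, Gsta2 by -3.09, Cyp2b10 by -2.92, Trp53inp1 by -3.01, Socs3 by 3.11, Fabp5 by 2.86 and Nr4a1 by -3.84.

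Splits of the same libraries into groups of the same sizes were counted, the real split included. Over both sex labels 100 were drawn, and within 1 sex or diet label all 35. No correction was made over comparisons. Chance is unlikely for ethanol against control at peak (3049 genes, 856 in the highest other split, 1 of 100 as large). Another split called more at early (1880, 3066, 2 of 100) and late resolution (1440, 2189, 2 of 100), leaving chance open. Within female-labelled libraries it is unlikely at peak (748, 9, 1 of 35) and early resolution (441, 262, 1 of 35). At late resolution it is not (277, 1914, 4 of 35). Within male-labelled libraries it is unlikely at peak (2635, 148, 1 of 35). The same holds at early (943, 10, 1 of 35) and late resolution (724, 320, 1 of 35). For the sex difference in the ethanol-labelled effect 3 of 100 splits were as large at peak (18, 3467). At late resolution 4 of 100 were (5, 1599), and at early resolution 7 of 100 (1, 3541), where chance cannot be excluded. Exchanging sex labels also breaks up the difference between sex labels itself, which widens the spread within groups. So chance stays open for the 18 and 5 genes. The change from peak to late resolution also had few splits as large (447, 3881, 3 of 100). But these splits ignore replicate numbers and, by exchanging stages, break up the stage difference. With the replicate block this count and that of the late sex difference were 0. The counts of 0 to early resolution and from early to late resolution were reached by 100 of 100 splits (highest 1706 and 4373). By limma these changes had 1879 and 354 genes at an unadjusted p under 0.05. For male against female controls another split called more (150, 1809, 2 of 100), so chance stays open. It is unlikely for the stage differences in controls (82, 19, 1 of 100, and 76, 9, 1 of 100). Between sex labels it is unlikely at peak (5729, 3208, 1 of 100) and late resolution (365, 68, 1 of 100). It is not at early resolution (67, 1957, 5 of 100). It is unlikely at peak within control-labelled (326, 68, 1 of 35) and ethanol-labelled libraries (5559, 3371, 1 of 35). It is unlikely for the change between sex labels to early (3582, 2799, 1 of 100) and late resolution (4105, 24, 1 of 100). Several other splits called many times the real count, and the cause was not tested.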

How the results depend on the processing

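The tests with median-of-ratios scaling and all comparisons of female-labelled with male-labelled libraries were chosen only after the result was seen, and the other settings were planned. Of 428 values under other settings, 279 stayed within 1.5 times the deposited-scale value and 149 moved by more. Pseudocount 2, division by totals, no trend and a robust trend moved no count by more than 1.5 times. Dividing by totals changes nothing, since the totals are equal. A count-based test was not run, because whole reads cannot be recovered from TPM and depth is unknown. Array weights ranged from 0.142 to 13.2 and their estimation stopped before it converged, so those counts are uncertain. Apart from thresholds that only remove genes, the cause of a move was not tested. In what follows the diet effect is the ethanol-labelled minus the control-labelled difference, and the sex-label difference is the female-labelled minus the male-labelled difference.

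With a pseudocount of 0.1, the number of genes was 0 (early) for the sex difference. Without a filter, the number of genes was 0 (early) and 9 (late) for the sex difference and 290 (peak to late) for the change of the diet effect. It was 91 for male against female controls. Without a filter the number of lists was 7 for the sex-label difference (late). With a mean of at least 5 TPM, the number of genes was 1617 (peak), 1075 (early), 914 (late), 381 (peak female), 1577 (peak male), 496 (early male) and 416 (late male) for the diet effect and 10 (peak) and 0 (early) for the sex difference. It was 279 (peak to late) for the change of the diet effect and 45 (peak to early) and 24 (peak to late) for control stages. It was 3213 (peak), 218 (late), 214 (peak control-labelled) and 3054 (peak ethanol-labelled) for the sex-label difference and 2174 (peak to early) and 2163 (peak to late) for the change of the sex-label difference. With a mean of at least 5 TPM the number of lists was 11 for the diet effect (late). Fewer genes were tested. With quantile normalization, the number of genes was 2423 (late), 461 (late female) and 1608 (late male) for the diet effect and 37 (peak), 0 (early) and 13 (late) for the sex difference. It was 13 (peak to early) and 1290 (peak to late) for the change of the diet effect and 717 for male against female controls. It was 195 (peak to early) and 43 (peak to late) for control stages and 3356 (peak), 243 (early), 1213 (late) and 3269 (peak ethanol-labelled) for the sex-label difference. It was 1878 (peak to early) and 2027 (peak to late) for the change of the sex-label difference. With quantile normalization the number of lists was 10 for the sex-label difference (peak). With median-of-ratios scaling, the number of genes was 2250 (late), 430 (late female) and 1349 (late male) for the diet effect and 47 (peak) and 0 (early) for the sex difference. It was 19 (peak to early) and 1369 (peak to late) for the change of the diet effect and 551 for male against female controls. It was 252 (peak to early) for control stages and 3587 (peak), 202 (early), 1071 (late) and 3551 (peak ethanol-labelled) for the sex-label difference. It was 1871 (peak to early) and 2312 (peak to late) for the change of the sex-label difference. With array weights, the number of genes was 4589 (peak), 4775 (early), 3712 (late), 2495 (peak female), 4348 (peak male), 1761 (early female), 4667 (early male) and 4575 (late male) for the diet effect and 2141 (peak), 0 (early) and 41 (late) for the sex difference. It was 2171 (peak to early), 2400 (peak to late) and 88 (early to late) for the change of the diet effect and 1949 for male against female controls. It was 1011 (peak to early) and 3617 (peak to late) for control stages and 2857 (early), 3505 (late) and 4789 (peak control-labelled) for the sex-label difference. It was 6007 (peak to early) for the change of the sex-label difference. With the libraries of the stage alone, the number of genes was 727 (late), 30 (late female) and 275 (late male) for the diet effect and 35 (peak), 2 (early) and 0 (late) for the sex difference. It was 9 (early) and 75 (late) for the sex-label difference. Fewer libraries entered the fit. With the libraries of the stage and sex alone, the number of genes was 347 (peak female), 173 (early female), 1 (late female) and 2589 (late male) for the diet effect. Only 7 or 8 libraries entered these fits. With the replicate block, the number of genes was 580 (late), 109 (late female) and 407 (late male) for the diet effect and 10 (peak), 0 (early) and 0 (late) for the sex difference. It was 0 (peak to late) for the change of the diet effect. This fit also left out the 3 libraries without a partner, and the effects of both changes were not separated. With a log2 difference of at least 1, the number of genes was 444 (peak), 306 (early), 269 (late), 301 (peak female), 804 (peak male), 263 (early female), 417 (early male), 183 (late female) and 353 (late male) for the diet effect and 139 (peak to late) for the change of the diet effect. It was 19 for male against female controls and 21 (peak to early) and 8 (peak to late) for control stages. It was 480 (peak), 17 (early), 34 (late), 135 (peak control-labelled) and 1300 (peak ethanol-labelled) for the sex-label difference and 687 (peak to early) and 756 (peak to late) for the change of the sex-label difference. This threshold only removes genes. At a false discovery rate of 0.01, the number of genes was 1782 (peak), 924 (early), 636 (late), 327 (peak female), 1348 (peak male), 227 (early female), 448 (early male), 121 (late female) and 317 (late male) for the diet effect and 3 (peak), 0 (early) and 0 (late) for the sex difference. It was 36 (peak to late) for the change of the diet effect and 23 for male against female controls. It was 18 (peak to early) and 0 (peak to late) for control stages and 3679 (peak), 13 (early), 27 (late), 104 (peak control-labelled) and 3337 (peak ethanol-labelled) for the sex-label difference. It was 1355 (peak to early) and 1891 (peak to late) for the change of the sex-label difference. This threshold only removes genes. By camera with an estimated correlation the number of lists was 2 for the diet effect (peak), 2 for the diet effect (early), 2 for the diet effect (late), 0 for the sex-label difference (peak), 0 for the sex-label difference (early) and 0 for the sex-label difference (late). By fry the number of lists was 11 for the sex-label difference (peak) and 1 for the sex-label difference (early).

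Over 493 counts with 1 library left out, 357 stayed within 1.5 times and 136 moved by more. 3049 for the diet effect (peak) ranged from 2572 to 3275. 1880 for the diet effect (early) became 1123 without early ethanol female 2 and 3016 without early ethanol female 1. 1440 for the diet effect (late) ranged from 966 to 2098. 748 for the diet effect (peak female) became 426 without peak ethanol female 1 and 960 without peak ethanol female 3. 2635 for the diet effect (peak male) ranged from 1773 to 2842. 441 for the diet effect (early female) became 287 without early ethanol female 2 and 563 without early ethanol female 1. 943 for the diet effect (early male) became 448 without early control male 2 and 1208 without early control male 1. 277 for the diet effect (late female) became 122 without late ethanol female 1 and 991 without late control female 1. 724 for the diet effect (late male) became 318 without late ethanol male 1 and 738 without late control male 1. 18 for the sex difference (peak) became 4 without peak control male 3 and 134 without peak ethanol female 3. 1 for the sex difference (early) became 0 without early control female 1 and 5 without early ethanol female 3. 5 for the sex difference (late) became 0 without late control female 1 and 10 without late control female 3. 0 for the change of the diet effect (peak to early) became 1072 without early ethanol female 1. 447 for the change of the diet effect (peak to late) became 95 without late ethanol female 1 and 1064 without late ethanol female 3. 0 for the change of the diet effect (early to late) became 1 without early control female 1. 150 for male against female controls became 58 without late control male 3 and 835 without late control female 4. 82 for control stages (peak to early) became 26 without early control male 4 and 119 without early control male 1. 76 for control stages (peak to late) became 7 without peak control male 1 and 904 without late control female 3. 5729 for the sex-label difference (peak) ranged from 4865 to 6254. 67 for the sex-label difference (early) became 16 without early ethanol female 2 and 206 without early ethanol female 3. 365 for the sex-label difference (late) became 25 without late ethanol female 1 and 1853 without late ethanol female 3. 3582 for the change of the sex-label difference (peak to early) became 1803 without early ethanol female 1 and 4790 without early ethanol female 3. 4105 for the change of the sex-label difference (peak to late) ranged from 3144 to 4813. 326 for the sex-label difference (peak control-labelled) became 120 without peak control male 1 and 314 without peak control female 1. 5559 for the sex-label difference (peak ethanol-labelled) ranged from 4087 to 6148. 0.823 for the overlap of diet effects (peak and early) ranged from 0.752 to 0.856. 0.73 for the overlap of diet effects (peak and late) ranged from 0.693 to 0.771. 0.91 for the overlap of diet effects (early and late) ranged from 0.878 to 0.92.

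Other omissions that moved a count by more than 1.5 times follow. For the change of the diet effect (peak to late) it was 293 and 232 without peak control female 1 and 4, 198 without peak ethanol female 3, 230, 194 and 987 without peak control male 1, 2 and 4, 258 without peak ethanol male 1, 870 and 257 without late control female 3 and 4, 182 without late control male 3, 223 and 241 without late ethanol male 2 and 3. For control stages (peak to late) it was 25, 347 and 18 without peak control female 1, 2 and 4, 12 and 693 without peak control male 2 and 4, 19, 15 and 664 without late control female 1, 2 and 4, 29, 21, 18 and 30 without late control male 1, 2, 3 and 4. For the sex difference (peak) it was 7 and 5 without peak control female 2 and 3, 9, 9 and 5 without peak ethanol female 1, 2 and 4, 7 and 6 without peak control male 1 and 2, 4 and 10 without peak ethanol male 1 and 4. For the sex-label difference (peak control-labelled) it was 137, 145 and 198 without peak control female 2, 3 and 4, 202 and 213 without peak control male 2 and 3. For male against female controls it was 86 without peak control female 3, 60 without peak control male 4, 89 without early control female 1, 67 and 70 without early control male 2 and 4, 235, 74 and 75 without late control male 1, 2 and 4. For control stages (peak to early) it was 40 and 42 without peak control female 3 and 4, 31, 45 and 50 without peak control male 1, 2 and 3, 45, 48 and 43 without early control female 1, 2 and 4, 37 without early control male 3. For the change of the diet effect (peak to early) it was 1 without peak control female 4, 3 without peak ethanol male 3. For the sex-label difference (early) it was 21 and 38 without early control female 1 and 3, 149 without early ethanol female 1, 34 and 24 without early control male 3 and 4, 199, 24 and 16 without early ethanol male 2, 3 and 4. For the diet effect (early male) it was 515 without early control male 4, 544 without early ethanol male 1. For the diet effect (late female) it was 181 and 132 without late control female 2 and 4, 177 without late ethanol female 3. For the sex difference (late) it was 0 without late control female 2, 0 and 1 without late ethanol female 1 and 3, 1 and 0 without late control male 3 and 4, 0, 2 and 0 without late ethanol male 1, 2 and 3. For the sex-label difference (late) it was 740, 49 and 985 without late control female 2, 3 and 4, 70 without late ethanol female 2, 189, 144 and 178 without late control male 2, 3 and 4, 51, 136 and 133 without late ethanol male 1, 2 and 3. For the diet effect (late male) it was 462, 470 and 406 without late control male 2, 3 and 4, 461 and 387 without late ethanol male 2 and 3. For the sex difference at early resolution 0 genes passed in 14 of 15 omissions by limma.

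Cyp2e1 changed sign for ethanol against control at early resolution, from 0.02 to -0.13 with median-of-ratios scaling, -0.01 without early control female 2 or early control male 4, -0.03 without early ethanol female 3 and -0.02 without early control male 2 (highest 0.09, without early control male 1). At late resolution it went from 0.08 to -0.10 with array weights. Between sex labels at peak Cyp2e1 went from 0.21 to -0.12 and Alb from 0.16 to -0.17 with median-of-ratios scaling. None of these values passed the threshold, and the cause was not tested. Over the alternatives the adjusted p of Cyp2e1 ran from 0.0015 to 0.72 at peak, 0.029 to 0.99 at early and 0.18 to 0.94 at late resolution. For Alb it ran from 0.011 to 1, 4.9e-06 to 1 and 0.00021 to 1, with the highest values set by quantile normalization, which gives the top transcript the same value in every library.

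Of 207 named results, 162 kept their side of the threshold in all single omissions and 43 lost a call in at least 1. The setting that lost most was the stage alone, with 25 of 168 weaker, then the replicate block with 17 of 116 and no filter with 16 of 207. Over the alternatives the adjusted p ran from 1e-04 to 0.14 for Tff3 and 0.00019 to 0.061 for Car14 (sex difference, peak), 0.0076 to 0.13 for Igfbp1 and 0.0018 to 0.086 for Mcm10 (change of the diet effect), and 0.00074 to 0.053 for G6pc (control stages, peak to late). It ran from 3.6e-06 to 0.062 for Gldc, 1e-06 to 0.062 for G6pdx and 0.00019 to 0.05 for Cd79b (late), and 0.04 to 0.32 for Ddx3y (male against female controls). In brackets below stands the number of fits with 1 library left out in which the call was lost. Tff3 (3 of 16), Car14 (1 of 16), H3f3b (11 of 16) and Tubb6 (10 of 16) lost a call for the sex difference (peak). Igfbp1 (3 of 30), Steap4 (15 of 30), Hcar2 (12 of 30), Pdk4 (18 of 30), Nr1d1 (14 of 30) and Gmnn (9 of 30) lost a call for the change of the diet effect (peak to late). G6pc (1 of 16), Fasn (10 of 16), Gstp1 (8 of 16) and Gstm3 (8 of 16) lost a call for control stages (peak to late). Elovl3 (12 of 24), Cyp2b9 (7 of 24) and Fos (4 of 24) lost a call for male against female controls. G6pc (8 of 16) and Gsta1 (12 of 16) lost a call for control stages (peak to early). Hspa5 (1 of 16) lost a call for the sex-label difference (peak). Aldh2 (4 of 15), Fos (1 of 15) and Cdk1 (1 of 15) lost a call for the diet effect (early). Arntl (1 of 15), Cyp8b1 (11 of 15), Clock (7 of 15), Fabp5 (8 of 15), Oas2 (6 of 15), Dmgdh (5 of 15) and Cd9 (6 of 15) lost a call for the sex-label difference (early). Sult3a2 (14 of 15) lost a call for the sex difference (early). G6pc (10 of 14), Errfi1 (8 of 14), Slc6a9 (9 of 14), 9430037G07Rik (13 of 14) and D17H6S56E-5 (7 of 14) lost a call for the sex difference (late). Igfbp1 (3 of 14), G6pc (3 of 14), Zbtb16 (5 of 14), Edem1 (5 of 14), Per1 (5 of 14) and Junb (9 of 14) lost a call for the sex-label difference (late). Tgfb1 (1 of 14) lost a call for the diet effect (late).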

Other observations

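The median-of-ratios factors were chosen only after the result was seen, and no hypothesis was tested in this part. Cyp7a1, which starts bile acid synthesis, stood at 0.319 ± 0.293 TPM (SD, n = 4) in control-labelled females and 0.389 ± 0.594 TPM (SD, n = 4) in ethanol-labelled females at peak. In males it stood at 1.27 ± 0.804 TPM with control and 0.125 ± 0.0775 TPM with ethanol (SD, n = 4 each). Across 971 genes over 100 TPM, the closest libraries were peak control female 2 and 3, with Pearson r = 0.9939. Of all pairs of libraries, 0 had identical values. Median-of-ratios factors ranged from -0.41 in late control female 4 to 0.33 in early ethanol female 3 and late ethanol female 3 on the log2 scale.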
